A study of Saccharomyces cerevisiae and Escherichia coli with 175 samples.

How the data were processed

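The series holds 175 samples, 10 of mRNA of Saccharomyces cerevisiae and the rest of cDNA cloned from it. The entry and destination vectors were carried in Escherichia coli and the later libraries in yeast. Polyadenylated RNA was taken with oligo(dT) beads and made into strand-marked RNA sequencing libraries, and the cloned cDNA was made into DNA sequencing libraries that do not mark the strand, per the labels' protocols. Reads were handled with HISAT2 and StringTie, per the submitters' processing notes, and their versions, settings and the genome build are not given in the sources used here. Each sample has a deposited gene abundance file with a TPM, an FPKM and a coverage value per gene, per the file headers.

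TPM (length-normalised transcript abundance) was the main measure, as the authors deposited it. The TPM columns sum to about double the usual total per sample, since assembled transcripts are listed beside annotated genes, so the values were treated as a signal, and the deposited signal over annotated genes summed to between 941266 and 1125121. For gene values, only the 6605 annotated entries found in every file were used. Of these 6576 are nuclear, 27 mitochondrial, 1 the ribosomal DNA and 1 the entry vector. The 4220 to 5894 assembled transcripts per file have no shared identity between samples and entered no comparison. FPKM (fragments scaled by gene length and library size), also deposited by the authors, served as another scaling. The ratio of deposited coverage to FPKM gave the aligned megabases reported as depth. Its median was taken over entries with an FPKM above 1, assembled transcripts included. Coverage times the gene length served only as another measure for the effective number of genes. Read counts are not given, so no count test was run and no counting interval was computed. Gene names came from the reference table of assembly R64, which matched 5919 identifiers and was used for names only. Coordinates are those of the files. Of the nuclear genes 770 are overlapped over at least 25% of their length by another annotated gene, and where such a gene is named the overlapping gene is given. No tRNA gene is in the files, so the list of nuclear tRNA genes had 0 members. Gene lengths are spans from start to end and include introns.

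Samples were grouped by the labels alone. The 1 sample without a day entered no comparison. Replicates were compared first. None of 153 replicate pairs had identical values, and their correlation on the log scale was 0.926 to 0.991. Nothing in the labels says that replicates are separate cultures, so p-values measure only the spread between these samples, which may be technical.

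Each comparison was fitted with limma (3.58.1, in R 4.3.3) on log2(TPM + 1), with eBayes and a mean-variance trend, over genes with a mean TPM of at least 5 in the samples of the fit. A gene was called with a Benjamini-Hochberg adjusted p under 0.05 and a log2 change of at least 1 either way. The 4 adjacent-stage mRNA comparisons shared 1 fit of all 10 mRNA samples. The cloning steps had the stage as a block. Each screen library was fitted by itself on its day 5 samples, and the mean over libraries, the F test of whether the effect differs between libraries, and the comparisons of day 5 with day 1 were fitted on all 5 libraries. Gene lists were tested with camera, with a preset correlation of 0.01 and again with an estimated correlation, on lists with at least 5 members tested, and p-values were adjusted over the lists of a comparison. The lists were early, middle and late spore wall genes of meiosis, cytosolic and mitochondrial ribosomal proteins, the nuclear-encoded respiratory chain, mitochondrial protein import, the galactose pathway, carbon source regulators, the Ras and protein kinase A pathway, growth brakes (inhibitors of the cell cycle and the mating pathway), the cytoskeleton, chaperones, glycolysis and fermentation, the TCA and glyoxylate cycle, core histones, and the mitochondrially encoded genes, which served only as a measure of carried-over DNA. Lists, tests, alternatives and the rule for naming genes were set before the data were examined.

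The rule named, for each mRNA comparison, the 6 largest rises and 6 largest falls among called genes with no overlap between groups and a mean TPM of at least 50 in the higher group. For cloning steps it named 8 and 8 with 1 direction in all 5 stages, for each library's screen 6 and 6 with at least 20 TPM, and for the mean over libraries up to 10 each way with 1 direction in all 5. It also named the 15 largest mean falls among genes called the same way in at least 3 libraries, and called list members as examples. Genes named outside it are said to be so. Not every gene the rule gives is printed.

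Scripts were tested on simulated data made from the real samples' means and spreads, with 200 genes changed by a log2 size of 1.5 or 3. Of 100 genes changed by 3, the fit found 97 to 100 in the mRNA comparisons (5977 genes simulated), 92 for the entry vector (5960), 74 for the destination vector (5479) and 80 for the pools (5527). It found 84 for the starvation library (3523), 80 for early (4726), 94 for meiosis I (3215), 92 for meiosis II (2468), 87 for late (3420) and 96 for the mean over libraries (5153). Of 100 changed by 1.5 it found 76 to 82, 52, 24, 45, 27, 45, 58, 64, 53 and 88 in the same order. The F test between libraries found 63 and 15 of 100, YPD day 5 against day 1 99 and 89, and YPGR day 5 against day 1 98 and 85. Unchanged genes called numbered at most 12 in any of these.

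Replicate numbers were checked for pairing by the correlation of same-numbered samples' deviations from their group means. In the starvation screen every pair exceeded 0.1 (0.22, 0.23 and 0.55). For day 5 against day 1 all 15 pairs did in each medium (0.19 to 0.8 in YPD, 0.31 to 0.8 in YPGR). By this rule the numbers were taken to pair those samples. The other screens did not meet it, nor did the mRNA stages, where 9 of 10 pairs of stages exceeded 0.1. In the starvation screen only 2 of 6 comparisons matched a sample best with its own number, so pairing there is uncertain. Such matches were 30 of 30 for day 5 against day 1 in each medium. In the early, meiosis I, meiosis II and late screens they were 2, 4, 6 and 5 of 6. The alternatives tried were a pseudocount of 5, no filter and a mean TPM of at least 20, median centring, FPKM, a replicate block, no stage block, 1 spread shared over libraries, and leaving out each replicate, stage or library in turn. Added after the data were seen were TPM rescaled over nuclear genes, leaving out overlapped genes, days 1 to 4, leaving out starvation replicate 3, the F test on genes tested in all 5 libraries, and camera with a replicate block where the numbers were taken to pair the samples. Other splits of the samples were drawn up to 100 times. Effective numbers of genes were compared by permutation in scipy 1.17.1 (Python 3.11.15, numpy 2.4.6, pandas 2.3.3). Figures were drawn with matplotlib 3.10.9, and files were read with the R package data.table (version 1.17.8).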

Results

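The series followed transcripts of budding yeast (Saccharomyces cerevisiae) from meiosis into complementary DNA (cDNA) expression libraries and on through a growth screen. Synchronous sporulating cultures were sampled at 5 stages, named starvation, early, meiosis I, meiosis II and late. Polyadenylated RNA was sequenced in 2 replicates per stage, giving 10 mRNA samples. cDNA made from each stage was moved into a Gateway entry vector, then into a destination vector with a galactose-inducible promoter, both carried in Escherichia coli, and last into yeast by electroporation. The cloned cDNA was sequenced as DNA in 1 sample per stage at each of these steps, so the cloning steps have replicates only across stages. Each of the 5 yeast libraries then grew in competition for up to 5 days in YPGR, a galactose medium that induces the cDNAs, or in YPD, a glucose medium that does not, with 3 replicates per medium and day. Of the 175 samples, 1 from the early library in YPGR carried no day and entered no comparison, and YPGR day 2 of that library has 2 replicates.

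Depth was read from the ratio of coverage to FPKM in the files, as aligned megabases. The mRNA samples had 761.7 to 1238.9 megabases (median 927.8), the entry vector samples 1153.8 to 2028.8 (median 1423.5), the destination vector samples 926.8 to 1657.2 (median 1195.6), the yeast pools 802.8 to 1363.1 (median 1099.5) and the 149 screen samples with a day 367.3 to 2441.6 (median 800.9). Read counts are not given in the sources used here, so no counting interval was computed. A gene was called where limma gave a Benjamini-Hochberg adjusted p under 0.05 and a log2 change of at least 1, on log2(TPM + 1), a scale that understates the change of low genes. Log2 changes are given with their standard error. Where the level of the samples' median gene differed by over 0.1 between the groups, changes are given after centring each sample on that gene. This holds for the mRNA stages, the first 2 cloning steps and the means over libraries. The level of the median gene is not the median change over genes, which centring raised in the means over libraries. That median went from 0.04 to 0.16 for YPGR against YPD. For day 5 against day 1 it went from -0.11 to 0.12 in YPD and from -0.06 to 0.24 in YPGR.

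Early against starvation compared starved cells with cells that had entered meiosis (2 samples against 2, same strain). Among called genes with at least 50 TPM, the 6 largest rises included genes of meiotic recombination and chromosome pairing. MEI5, which helps load the meiotic recombinase, rose by 8.56 ± 0.27 on the log2 scale (adjusted p = 1.41e-07). ECM11, part of the synaptonemal complex, rose by 8.15 ± 0.16, NDJ1, a meiotic telomere protein, by 7.98 ± 0.17, MEK1, a meiotic checkpoint kinase, by 7.72 ± 0.21, and YLR445W by 7.65 ± 0.26. DMC1, the meiotic recombinase itself, rose by 7.68 ± 0.20 (adjusted p = 4.98e-08) to a mean of 2500 TPM. The histidine biosynthesis gene HIS4 fell by 4.83 ± 0.36 (adjusted p = 1.59e-05), with the biotin transporter VHT1 at -4.44 ± 0.25 and ICY2 at -4.50 ± 0.30. YOR302W, the short reading frame in the leader of the arginine gene CPA1, fell by 6.47 ± 1.43, and YNL103W-A, which overlaps the leucine gene LEU4, fell by 5.98 ± 1.10. YKL065W-A fell by 4.64 ± 0.75.

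All 33 early meiotic genes rose, also when adjusted over the list alone, with a median of 5.67 (camera adjusted p = 2.95e-25, and adjusted p = 0.164 with an estimated correlation). All 8 core histone genes rose, also when adjusted over the list alone, with HTB2 up by 5.94 ± 0.17, HTA2 by 4.36 ± 0.45 and HHF1 by 3.57 ± 0.27 (camera adjusted p = 6.18e-05, and adjusted p = 0.449 with an estimated correlation). Of 35 middle meiotic genes, 21 rose and 1 fell, also adjusted over the list alone, and 16 and 1 after centring (camera adjusted p = 0.000517, and adjusted p = 0.508 with an estimated correlation). Among them were AMA1, a meiotic activator of the anaphase-promoting complex, at 4.44 ± 0.18, MPC54, a spindle pole component, at 3.16 ± 0.19, and NDT80, the transcription factor of the middle genes, at 2.71 ± 0.23. Of 20 chaperone genes 12 rose, also adjusted over the list alone, and 10 rose and 1 fell after centring, led by HSP82 at 3.00 ± 0.22 and HSC82 at 1.77 ± 0.22 (camera adjusted p = 0.00225, and adjusted p = 0.508 with an estimated correlation). Glycolysis and fermentation fell, with 14 of 19 genes down after centring and 10 down and 1 up before it, against 12 and 1 adjusted over the list alone (camera adjusted p = 1.78e-05, and adjusted p = 0.508 with an estimated correlation). ENO2, an enolase, fell by 4.04 ± 1.37, with PDC1, pyruvate decarboxylase, at -3.85 ± 0.46 and CDC19, pyruvate kinase, at -3.60 ± 0.61. Of 138 cytosolic ribosomal protein genes, 49 fell and 1 rose, the same counts adjusted over the list alone, and 79 fell after centring (camera adjusted p = 2.62e-17, and adjusted p = 0.508 with an estimated correlation). RPS10A fell by 2.61 ± 0.28, with RPL37A at -2.52 ± 0.41, while RPL15B rose by 1.94 ± 0.19. The nuclear-encoded respiratory chain had 11 of its 40 genes down after centring, and 3 down and 1 up before it (3 down adjusted over the list alone, camera adjusted p = 0.00302, and adjusted p = 0.508 with an estimated correlation). Cytoskeleton genes did not pass camera as a group (adjusted p = 0.0604), though 9 of 18 rose, also adjusted over the list alone, and 8 rose and 1 fell after centring, among them the tubulin genes TUB1 at 3.30 ± 0.18 and TUB2 at 2.63 ± 0.21.

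Of 6056 genes tested in the mRNA comparisons, 1238 rose and 538 fell from starvation to early. Centring took off a shift of 0.34 and left 805 up and 909 down. On FPKM 918 rose and 681 fell.

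Meiosis I against early compared prophase cells with cells in the divisions, and the strain differed between these stages, so stage and strain cannot be told apart here. SPO19, a prospore membrane protein, rose by 7.85 ± 0.22 (adjusted p = 6.12e-08) to a mean of 12800 TPM, PES4, an RNA-binding regulator of meiotic transcripts, by 7.67 ± 0.28, SRD1 by 8.28 ± 0.21, YGL230C by 7.71 ± 0.33 and YGR273C by 7.67 ± 0.20. GAL7, an enzyme of galactose breakdown, rose by 8.12 ± 0.71 (adjusted p = 1.84e-05). Among the falls, the copper-binding metallothionein CUP1-1 fell by 5.08 ± 0.34 (adjusted p = 3.36e-06), with its near-identical copy CUP1-2 at -5.14 ± 0.28. YHR052W-A, which overlaps CUP1-1, fell by 5.89 ± 0.45. LEU1, an enzyme of leucine synthesis, fell by 5.06 ± 0.57, with histone HTA2 at -5.04 ± 0.45 and IME4, the mRNA adenosine methyltransferase, at -5.02 ± 0.19 (adjusted p = 1.58e-07).

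After centring all 35 middle meiotic genes rose, with a median of 6.17, led beyond SPO19 and PES4 by SPS22 at 7.46 ± 0.29, SPS2 at 7.45 ± 0.48 and the septin SPR3 at 7.08 ± 0.23 (camera adjusted p = 2.45e-30, and adjusted p = 0.114 with an estimated correlation). Of 19 late spore wall genes, 15 rose and 3 fell, with the chitin deacetylase CDA2 at 6.96 ± 0.30 and the dityrosine transporter DTR1 at 6.39 ± 0.30 (camera adjusted p = 2.02e-08, and adjusted p = 0.114 with an estimated correlation). Of 10 galactose genes, 7 rose and 1 fell. The transporter GAL2 rose by 5.86 ± 0.24, GAL10 by 3.76 ± 0.20, the repressor GAL80 by 3.05 ± 0.18 and the galactokinase GAL1 by 2.92 ± 0.22, while PGM1 fell by 1.88 ± 0.22 (camera adjusted p = 0.000398, and adjusted p = 0.217 with an estimated correlation). Of 74 mitochondrial ribosomal protein genes, 35 rose and 1 fell, among them MRPS17 at 4.59 ± 0.19 and MRPL37 at 4.36 ± 0.27 (camera adjusted p = 1.38e-07, and adjusted p = 0.368 with an estimated correlation). Early meiotic genes turned down, with 23 falling and 1 rising. The axis protein HOP1 fell by 3.16 ± 0.27, with the cohesin REC8 at -2.71 ± 0.26 and DMC1 at -2.67 ± 0.20 (camera adjusted p = 3.75e-05, and adjusted p = 0.388 with an estimated correlation). Of the 8 histone genes 7 fell, with HTB2 at -3.63 ± 0.17 (camera adjusted p = 0.00774, and adjusted p = 0.388 with an estimated correlation). Before centring, and equally when adjusted over the list alone, 34 middle genes rose, 14 spore wall genes rose and 3 fell, 6 galactose genes rose and 1 fell, 17 mitochondrial ribosomal genes rose and 4 fell, and 30 early meiotic genes and 8 histones fell. Cytosolic ribosomal proteins had a median of 0.55 after centring, -0.09 before it and 0.13 on FPKM, so its sign depends on the scaling. All tested genes had medians of -0.16, -0.8 and -0.54 on the same scales, so the list lay above them on each. After centring 27 rose, against 12 up and 8 down before it and 8 and 4 adjusted over the list alone (camera up, adjusted p = 0.00359, and adjusted p = 0.891 with an estimated correlation). No group call was made for the Ras and protein kinase A pathway (camera adjusted p = 0.426), though the cyclase partner SRV2 fell by 2.57 ± 0.28, with the kinase YAK1 at -2.11 ± 0.17. Nor was one made for carbon source regulators (adjusted p = 0.972), where HXK2 rose by 2.59 ± 0.40 and HAP4 by 2.39 ± 0.19, or for growth brakes (adjusted p = 0.426), where the mating pathway genes STE4 and STE5 rose by 3.90 ± 0.21 and 2.70 ± 0.18 and the mitotic inhibitor kinase SWE1 fell by 2.22 ± 0.30.

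In this comparison 772 genes rose and 2578 fell, and after centring, which took off a shift of -0.64, 1257 rose and 1357 fell.

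Meiosis II against meiosis I compared the divisions within 1 strain. SWC5, part of a chromatin remodelling complex, rose by 4.28 ± 0.67 (adjusted p = 0.00253). The lipase TGL5 rose by 2.72 ± 0.25, GDS1 by 2.70 ± 0.18, the GATA-type factor GAT4 by 2.59 ± 0.40, the replication protein PSF3 by 2.51 ± 0.17 and MEH1 by 2.49 ± 0.19. Of the ATP synthase genes, ATP20 fell by 2.63 ± 0.33 (adjusted p = 0.00134) and TIM11, despite its name one of them, fell by 2.59 ± 0.41. CUP1-1 fell by 2.59 ± 0.34, with YPR158W at -2.63 ± 0.22 and the a-agglutinin subunit AGA2 at -2.38 ± 0.34. RPL41B was at -2.60 ± 0.95 and lost its call on centring (adjusted p = 0.0645).

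Cytosolic ribosomal proteins fell in 101 of 138 genes, 104 adjusted over the list alone with 1 up, and 45 after centring with 1 up. RPL39 fell by 4.05 ± 0.65, with RPS16A at -2.19 ± 0.23 and RPL24A at -2.17 ± 0.34 (camera adjusted p = 2.9e-09, and adjusted p = 0.626 with an estimated correlation). Early meiotic genes fell in 27 cases and in 18 after centring, with HOP2, a strand exchange factor, at -2.37 ± 0.38 (camera adjusted p = 6.52e-09, and adjusted p = 0.626 with an estimated correlation). In the respiratory chain 27 genes fell, 16 after centring with 1 up, including SDH3 of succinate dehydrogenase at -2.26 ± 0.31 and COX8 of cytochrome oxidase at -2.07 ± 0.25 (camera adjusted p = 6.49e-06, and adjusted p = 0.626 with an estimated correlation). TCA cycle genes fell in 9 cases, 4 after centring with 1 up, with fumarase FUM1 at -1.87 ± 0.22 (camera adjusted p = 0.0133, and adjusted p = 0.626 with an estimated correlation). Chaperones fell in 9 cases, 6 after centring, with CPR6 at -1.90 ± 0.30 (camera adjusted p = 0.00637, and adjusted p = 0.626 with an estimated correlation). Cytoskeleton genes fell in 9 cases, 2 after centring with 1 up (camera adjusted p = 0.0466, and adjusted p = 0.626 with an estimated correlation). Middle meiotic genes had a centred median of 0.64, with 8 up after centring, and 3 down before it or 2 adjusted over the list alone (camera up, adjusted p = 0.00175, and adjusted p = 0.626 with an estimated correlation). The mitochondrial ribosomal proteins had a median of -0.16 before centring, 0.37 after it and 0 on FPKM, so its sign rests on the scaling. All tested genes had medians of -0.5, 0.03 and -0.32 on the same scales, so the list lay above them on each. Before centring 13 of its genes fell, and after it 11 rose and 5 fell (camera up, adjusted p = 0.0358, and adjusted p = 0.626 with an estimated correlation). The Ras pathway genes had a median of 0.04 but a mean of -0.07, with 1 up and 2 down before centring and 4 up after it (camera up, adjusted p = 0.0446, and adjusted p = 0.626 with an estimated correlation). Adjusted over the list alone, the counts before centring were unchanged for the lists where none is given.

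Here 115 genes rose and 1519 fell. After centring, which took off a shift of -0.54, 525 rose and 515 fell, and with a pseudocount of 5 in place of 1 the total was 1030.

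Late against meiosis II covered spore maturation, with the late samples taken from a mix of both strains. Stage and strain therefore cannot be told apart here either. DIT1, which makes the dityrosine of the outer spore wall, rose by 8.68 ± 0.24 (adjusted p = 4.56e-07) to a mean of 3230 TPM. The stress gene DDR2 rose by 7.01 ± 0.37 to 7010 TPM, YDL218W by 6.80 ± 0.21 and CUP1-1 by 6.74 ± 0.34. YHR054W-A and YHR052W-A, which overlap the metallothionein copies CUP1-2 and CUP1-1, rose by 6.57 ± 0.48 and 6.40 ± 0.45. IOC3 of a chromatin remodelling complex fell by 3.04 ± 0.25 (adjusted p = 5.34e-05), with the cytokinesis protein HOF1 at -2.95 ± 0.19, ORM1, a regulator of sphingolipid synthesis, at -2.58 ± 0.22 and ZPS1 at -2.52 ± 0.23. YFL032W fell by 4.03 ± 1.34, with YOL134C, which overlaps HRT1, at -2.63 ± 0.22.

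Cytosolic ribosomal proteins rose in 95 of 138 genes, 96 adjusted over the list alone, and 79 after centring with 2 down. RPS21A rose by 2.79 ± 0.51, RPL24A by 2.67 ± 0.34 and RPS9B by 2.60 ± 0.21 (camera adjusted p = 1.51e-10, and adjusted p = 0.734 with an estimated correlation). Middle meiotic genes fell in 27 of 35 cases after centring and 21 before it, with the B-type cyclin CLB1 at -2.02 ± 0.22 and the septin SPR28 at -1.96 ± 0.18 (camera adjusted p = 1.77e-08, and adjusted p = 0.61 with an estimated correlation). Mitochondrial ribosomal proteins fell in 34 cases with 1 up after centring, against 18 and 4 before it, with MRPL32 at -2.11 ± 0.26 and MRPL6 up by 1.92 ± 0.32 (camera adjusted p = 1.71e-06, and adjusted p = 0.61 with an estimated correlation). Galactose genes fell in 9 cases with 1 up after centring, against 4 and 1 before it and 5 and 1 adjusted over the list alone. GAL80 fell by 2.48 ± 0.18, with the activator GAL4 at -1.67 ± 0.30, while PGM1 rose by 1.28 ± 0.22 (camera adjusted p = 0.00212, and adjusted p = 0.61 with an estimated correlation). Early meiotic genes had 15 up and 1 down, 5 and 2 after centring, led by IME4 at 3.32 ± 0.19 (camera up, adjusted p = 0.00827, and adjusted p = 0.734 with an estimated correlation). The late spore wall list split. The spore wall gene SPS100 rose by 5.64 ± 0.34, FMP45 by 4.26 ± 0.38 and DIT2 by 3.19 ± 0.23, while OSW2 fell by 2.43 ± 0.19. Its 19 genes had 6 up and 5 down after centring, a median of -0.04 (-0.44 after centring and 0.05 on FPKM) and a mean of 1.03 (camera adjusted p = 0.972). Adjusted over the list alone, the counts before centring were unchanged for the early, middle, mitochondrial ribosomal and spore wall lists, the last with 6 up and 4 down.

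From meiosis II to late, 1500 genes rose and 532 fell. With a shift of 0.40 taken off by centring, 1005 rose and 1197 fell.

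**Figure D1:**
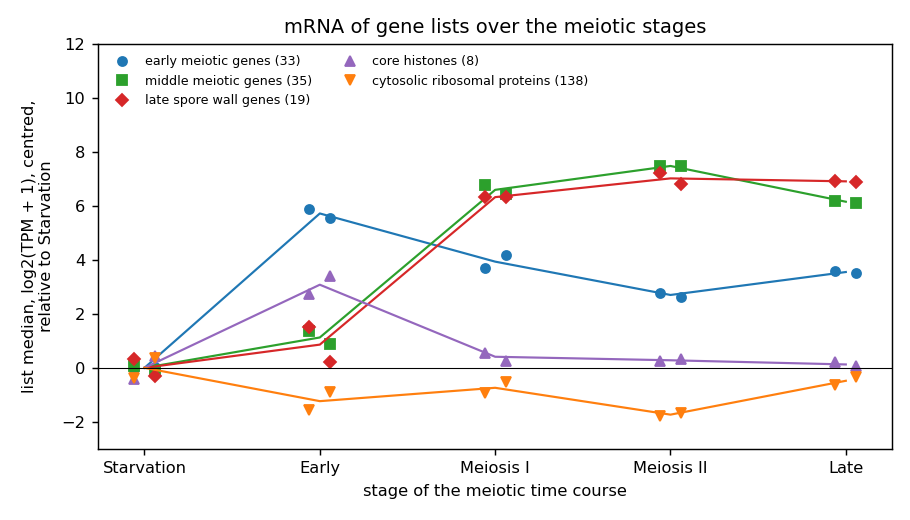
Median log2(TPM + 1) of 5 gene lists in each mRNA sample, centred on the sample's median gene and set relative to the starvation mean, by stage, with 1 point for each of 2 replicates and lines joining the stage means. Early meiotic genes reach 5.88 and 5.56 at the early stage and middle meiotic genes 7.47 and 7.49 at meiosis II, and without centring the ribosomal protein step from early to meiosis I turns from 0.55 to -0.09.

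Entry vector against mRNA asked which transcripts were gained or lost when cDNA was cloned, with the stage as a block (5 samples against 10). The ribosomal protein genes RPS26A and RPS30A fell, at -5.88 ± 0.64 (adjusted p = 1.48e-05) and -5.23 ± 0.61, with the outer membrane translocase subunit TOM5 at -5.78 ± 0.61. MRS11, a small carrier of the mitochondrial intermembrane space, fell by 5.51 ± 0.57, with DAD4 of the kinetochore at -5.45 ± 0.61, cytochrome c isoform CYC7 at -5.27 ± 0.60, ATP15 of ATP synthase at -5.27 ± 0.62 and YDR379C-A at -5.73. Of the 8 rises named, 7 were of reading frames that overlap other genes. YDR371C-A, which overlaps CTS2, rose by 5.85 ± 0.78 (adjusted p = 4.38e-05), YPL135C-A, which overlaps ISU1, by 5.33 ± 0.55, YDR187C, which overlaps CCT6, by 3.95 ± 0.48, YCL041C, without such an overlap, by 4.20 ± 0.56, YLR437C-A (CAR2) by 3.84, YPL222C-A (FMP40) by 3.83, YDR433W (NPL3) by 3.57 and YNL103W-A (LEU4) by 3.52, with the overlapped gene in brackets. The DNA libraries do not mark the strand, so these 7 cannot be told apart from the genes they overlap.

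Falls were more common among short genes. Of 1086 genes with a length under 500 bp (introns included) 60.6% fell, of 1515 genes from 500 to under 1000 bp 55.8%, of 2138 genes from 1000 to under 2000 bp 26.2%, and of 1230 longer genes 28.0%. With TPM rescaled over nuclear genes these shares were 43.2%, 26.3%, 5.2% and 4.5%. The centred medians of these classes were -1.08, -0.66, 0.31 and 0.05. By list, 69 cytosolic ribosomal protein genes fell and 5 rose after centring, against 106 and 1 before it and 109 and 2 adjusted over the list alone, with RPS30B at -4.60 ± 0.65 (camera adjusted p = 4.83e-08, and adjusted p = 0.28 with an estimated correlation). Of 8 histone genes, all fell before centring and 7 after it, with HTA1 at -4.01 ± 0.66 and HTB1 at -3.03 ± 0.45 (camera adjusted p = 0.000234, and adjusted p = 0.372 with an estimated correlation). Mitochondrial ribosomal proteins fell in 28 cases and rose in 2 after centring, against 49 falls before it and 53 adjusted over the list alone (camera adjusted p = 0.000234, and adjusted p = 0.255 with an estimated correlation). In the respiratory chain 19 genes fell and 5 rose, against 27 and 2 before centring (camera adjusted p = 0.000409, and adjusted p = 0.255 with an estimated correlation), and in mitochondrial import 13 fell and 3 rose, against 19 and 2 before it, with TOM7 at -4.38 ± 0.51 (camera adjusted p = 0.0116, and adjusted p = 0.255 with an estimated correlation). Chaperone, TCA cycle and glycolysis genes had centred medians of 1.14, 1.02 and 0.76, against -0.14 for all tested genes. On FPKM their medians were -0.66, -0.78 and -0.81, against -1.7 for all tested genes. The sign of these medians thus turned with the scaling, while the lists lay above the median of all tested genes on both scales. After centring 10 chaperone genes rose and 1 fell, against 5 and 4 before it, with SSA2 at 3.27 ± 0.43, YDJ1 at 2.59 ± 0.44 and HSP10 at -3.66 ± 0.49 (camera up, adjusted p = 0.000234, and adjusted p = 0.175 with an estimated correlation). The TCA and glyoxylate genes KGD2 and ICL1 rose by 2.40 ± 0.42 and 2.28 ± 0.43 among 7, against 3 up and 3 down before centring (camera up, adjusted p = 0.00457, and adjusted p = 0.255 with an estimated correlation). ADH1 and GLK1 rose by 2.67 ± 0.43 and 2.51 ± 0.46 among 6 glycolysis and fermentation genes, against 2 up and 2 down before centring (camera up, adjusted p = 0.00306, and adjusted p = 0.475 with an estimated correlation). Adjusted over the list alone, the counts before centring were the same for the histones, respiratory chain, import, chaperones and TCA cycle, and 2 up and 1 down for glycolysis.

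Of 5969 genes tested, 196 rose and 2409 fell. With 1 stage left out 83 to 307 rose. The entry vector's own sequence is listed as a gene and took a mean of 43.2% of the TPM in these samples, and with TPM rescaled over nuclear genes 475 rose and 1035 fell. After centring, which took off a shift of -0.99, 658 rose and 925 fell, and without the stage block 953 genes were called. Kit and molecule (RNA or DNA) differed along with the cloning step.

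**Figure D2:**
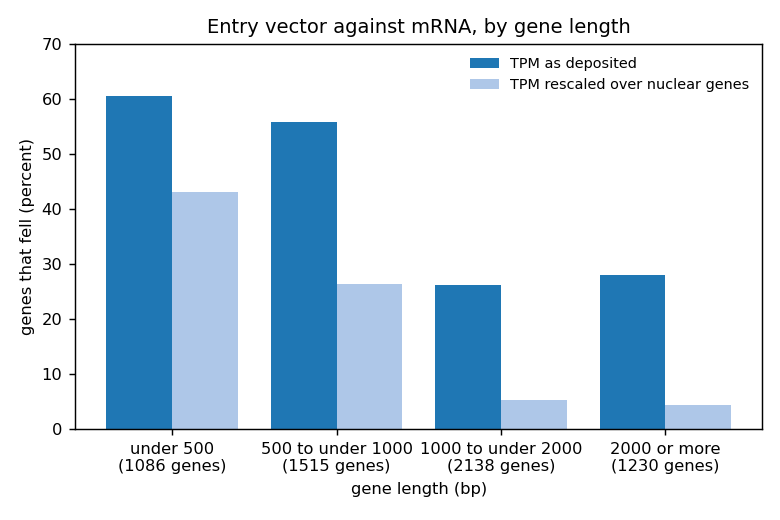
Percent of tested genes that fell from mRNA to entry vector, by gene length in base pairs, with TPM as deposited (dark bars) and rescaled over nuclear genes (light bars). The share falls from 60.6% of 1086 genes under 500 bp to 28.0% of 1230 genes of 2000 bp or more with TPM as deposited.

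Destination vector against entry vector compared the same libraries before and after the transfer between plasmids (5 pairs, stage as a block). Glucokinase GLK1 rose by 1.83 ± 0.24 (adjusted p = 0.00386), YCL042W, which overlaps it, by 2.17, and PAM1 by 2.86 ± 0.52. The mitochondrial cyclophilin CPR3, YJR056C, histone HTA1, the phosphatase inhibitor YPI1 and the actin-severing protein COF1 were at 2.34, 2.24, 2.22, 2.00 and 1.98, but each lost its call on centring. The hexose transporter HXT5 fell by 3.53 ± 0.42 (adjusted p = 0.00227), with the arginine permease CAN1 at -3.41 ± 0.49 and the Rab protein YPT52 at -3.13 ± 0.53. Reading frames inside other genes fell too, YLR154C-G (within RDN1) at -6.11 ± 0.66, YPL135C-A (ISU1) at -5.11, YDR371C-A (CTS2) at -4.95, YPL182C (CTI6) at -3.53 and YPL222C-A (FMP40) at -3.16. Histone genes lay high under each scaling, with medians from 0.62 to 2.38, and 4 of 8 passed limma's test before centring, 7 adjusted over the list alone and none after centring (camera adjusted p = 0.000191, and adjusted p = 0.278 with an estimated correlation). TCA and glyoxylate genes had 6 rises before centring, also adjusted over the list alone, and none after it, with 11 members under an unadjusted p of 0.05 in limma, and their median went from 0.65 to -0.16 with TPM rescaled over nuclear genes (camera up, adjusted p = 8.18e-05, and adjusted p = 0.278 with an estimated correlation). Camera also put the spore wall genes and the respiratory chain (adjusted p = 0.00739 each), chaperones (0.013), middle (0.017) and early (0.0184) meiotic genes, and cytoskeleton and glycolysis (0.0473 each) above the rest, but none with an estimated correlation (adjusted p from 0.278 to 0.676).

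The direction of this step as a whole turned with the scaling. The entry vector's own sequence took a mean of 43.2% of TPM in the entry vector samples and 0.0362% in the destination vector samples. Its loss by itself raises the TPM of other genes. The excess of rises with TPM as deposited was absent with TPM rescaled over nuclear genes, which leaves that sequence out. Of 5497 genes tested 268 rose and 38 fell (166 to 270 and 20 to 33 with 1 stage left out), after centring (a shift of 0.29) 55 and 39, on FPKM 2060 and 10, and with TPM rescaled over nuclear genes 3 and 54. Without the stage block limma called 0 genes (60 at an unadjusted p under 0.05), and without the early stage 190.

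Yeast pool against destination vector compared plasmids in bacteria with the pools of transformed yeast. HLR1, listed as YDR528W, was the 1 gene called by limma among 5526, and it is named because the count is 1. It rose by 5.75 ± 0.44 (adjusted p = 0.0018). Its TPM in the pools was 340, 600, 292, 295 and 361 from starvation to late, against 15.1, 25.8, 3.35, 1.46 and 2.09 in the destination vector. After centring PAM1 was called as well, at -4.53 ± 0.63. At an unadjusted p under 0.05 limma gave 565 genes. Middle meiotic and late spore wall genes lay higher in the pools by medians of 1.00 and 1.09, though limma called none of their members (12 and 7 at an unadjusted p under 0.05). Camera gave adjusted p = 2.06e-07 for the middle genes and 2.88e-05 for the spore wall genes, and adjusted p = 0.68 with an estimated correlation for both. The difference was uneven, since the middle genes' medians were 3.09 in the starvation library and 0.68 in the early library, against 0.06, 0.15 and 0.25 in the meiosis I, meiosis II and late libraries. The spore wall medians were 3.56, 0.82, -0.06, 0.16 and 0.12.

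The screens asked which cDNAs changed in abundance when their expression was induced. In each library, day 5 in YPGR was set against day 5 in YPD (3 samples against 3). What was sequenced is the plasmid cDNA, so a value here is the share of a cDNA in the population and not the expression of a gene.

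In the starvation library the phosphatase gene SIT4 rose by 4.41 ± 0.70 (adjusted p = 0.00588), PMU1 by 3.53 ± 0.74, the tropomyosin TPM2 by 2.34 ± 0.53, YLR297W by 2.21 ± 0.30, YPL229W by 2.07 ± 0.49 (adjusted p = 0.0519 with a replicate block) and NSE1, of the Smc5-Smc6 complex, by 1.69 ± 0.32. The ribosomal protein RPS12 fell by 6.60 ± 0.53 (adjusted p = 0.000219), with the mitochondrial ribosomal protein MRPL27 at -6.51 ± 0.60, the outer membrane protein FUN14 at -6.50 ± 0.62, FMP51 at -6.67 ± 0.63, OPI10 at -6.54 ± 0.56 and the glutathione transferase GTT1 at -6.51 ± 0.55. Of the mitochondrial ribosomal proteins, 3 of 31 genes tested fell, 6 adjusted over the list alone, including RSM28 at -6.29 ± 0.58 and RSM24 at -4.68 (camera adjusted p = 0.00188, and adjusted p = 0.247 with an estimated correlation). The respiratory chain fell in 5 of 27, 7 adjusted over the list alone, including ATP16 at -3.08, QCR6 at -2.51 and RIP1 at -1.69 (camera adjusted p = 0.000129, and adjusted p = 0.106 with an estimated correlation). In total 7 genes rose and 132 fell of 3605, and 17 and 174 with a replicate block. Without YPD replicate 1 limma called 48 and without YPD replicate 2 it called 53, with no filter on TPM 78, and with 1 spread shared over all libraries 313, of which 78 rose. With 1 sample left out 2 to 12 rose.

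In the early library, YPR063C rose by 3.77 ± 1.01, the chromatin remodeller CHD1 by 3.01 ± 0.61 (adjusted p = 0.0142), the dynactin subunit NIP100 by 2.90 ± 0.71, YBR116C, which overlaps TKL2, by 2.82 ± 0.52, YOL159C by 2.70 ± 0.65 and the deadenylase subunit PAN3 by 2.35 ± 0.54. MGR2, of the inner membrane translocase, fell by 7.20 ± 0.57 (adjusted p = 9.87e-05), with the release factor methyltransferase MTQ2 at -7.07 ± 0.55, the vesicle cargo protein EMP24 at -6.77 ± 0.63, YGR203W at -6.45 ± 0.67 and CSM1, of the monopolin complex, at -6.31 ± 0.59. Of 37 respiratory chain genes 11 fell, 15 adjusted over the list alone, with COX7 at -4.48 ± 0.43 and RIP1 at -3.98 (camera adjusted p = 2.24e-07, and adjusted p = 0.0432 with an estimated correlation). Of 42 mitochondrial ribosomal proteins 9 fell, also adjusted over the list alone, with RSM25 at -5.65 and MRPS8 at -5.60 (camera adjusted p = 0.000413, and adjusted p = 0.05 with an estimated correlation). In mitochondrial import 6 of 18 fell, 9 adjusted over the list alone, with TIM17 at -6.09 and TIM9 at -5.11 (camera adjusted p = 3.13e-05, and adjusted p = 0.05 with an estimated correlation). Of 83 cytosolic ribosomal proteins 14 fell and 1 rose, 17 and 2 adjusted over the list alone, with RPP0 at -6.12 and RPS4B at -5.23 (camera adjusted p = 0.00309). Core histones lay higher as a group with the same camera adjusted p, though limma called none of them (3 at an unadjusted p under 0.05), and for both lists the adjusted p was 0.107 with an estimated correlation. Of the cytoskeleton genes, profilin, PFY1, rose by 1.23 ± 0.25 and actin, ACT1, fell by 1.31 ± 0.20. In total 42 genes rose and 286 fell of 4790. Leaving out a YPD replicate gave 198, 188 and 199 calls for replicates 1, 2 and 3, and 1 spread shared over all libraries gave 590, of which 180 rose. With 1 sample left out 11 to 33 rose.

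In the meiosis I library, YKT6, a SNARE protein, rose by 2.76 ± 0.60 (adjusted p = 0.0117), the TFIIH subunit TFB3 by 2.44 ± 0.59, YCL002C by 2.37, the phosphatase subunit PSY4 by 2.32 ± 0.61, the vacuolar reductase FRE6 by 2.31 ± 0.51 and YSC83 by 1.92. RPS12 fell by 7.22 ± 0.46 (adjusted p = 1.15e-05), with YKL018C-A at -6.95 ± 0.48, YGL069C, which overlaps the mitochondrial ribosomal gene MNP1, at -6.52 ± 0.39, the transcription factor CAD1 at -6.45 ± 0.51, the import channel TOM40 at -6.42 ± 0.53 and MRPL20 at -5.99 ± 0.61. Mitochondrial ribosomal proteins fell in 17 of 43 genes, 18 adjusted over the list alone, with MRPS5 at -5.34 and MRPL22 at -5.06 (camera adjusted p = 9.93e-05, and adjusted p = 0.0873 with an estimated correlation). Import genes fell in 6 of 15, with TIM44 at -5.33 and TIM22 at -5.10, with a mean of -1.83 but a median of -0.05, or 0.03 after centring (camera adjusted p = 0.0498, and adjusted p = 0.224 with an estimated correlation). CYT1 of the respiratory chain fell by 4.26 (6 of 29 fell, camera adjusted p = 0.054). Of 14 Ras and protein kinase A genes 5 fell, among them the stress factor MSN2 at -4.12 and RAS1 at -2.30, without a group call (camera adjusted p = 0.0826). ACT1 fell by 4.85, with the growth inhibitors AMN1 and WHI5 at -3.11 and -2.64. Adjusted over the list alone, the import, respiratory chain and Ras pathway counts were the same. In total 27 genes rose and 295 fell of 3252. Without YPGR replicate 1, 2 or 3 the rises numbered 16, 11 and 12, and with 1 spread shared over all libraries 68.

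In the meiosis II library, YGL146C rose by 4.01 ± 0.65 (adjusted p = 0.00228), SET3, of a histone deacetylase complex, by 2.93 ± 0.83, the cyclin PCL9 by 2.65 ± 0.68, KKQ8 by 2.33, SLM2 by 2.25 ± 0.58 and NBP2 by 2.21 ± 0.50. PHO88 fell by 7.03 ± 0.52, with TIM22, the carrier translocase, at -7.03 ± 0.50 (adjusted p = 1.92e-05), the cargo receptor ERV14 at -6.85 ± 0.47, GMH1 at -6.83 ± 0.47, MRPL20 at -6.74 ± 0.50 and YCP4 at -6.62 ± 0.44. Of the mitochondrial ribosomal proteins 9 of 38 genes fell, 9 with 1 up adjusted over the list alone, with PET123 at -5.96 and RSM25 at -5.80, but the list's median was 0.01 and its mean -0.91 (camera adjusted p = 0.186). The respiratory chain fell in 5 of 21 genes, with ATP3 at -5.28 and SDH4 at -2.62 (camera adjusted p = 0.214). Import genes fell in 6 of 14, with TIM44 at -5.53 (camera adjusted p = 0.0281, and adjusted p = 0.27 with an estimated correlation). Middle meiotic genes lay higher with the same pair of p-values, though limma called none of them (12 at an unadjusted p under 0.05). COF1 and ABP1 of the actin cytoskeleton fell, at -2.12 and -2.01, with the phosphodiesterase PDE2 of the Ras pathway at -2.94. The respiratory chain and import counts were the same adjusted over the list alone. In total 29 genes rose and 203 fell of 2500. Without YPGR replicate 1 or 3 the rises numbered 17 and 19, and with a shared spread 59.

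In the late library, the stress transcription factor MSN4 rose by 3.17 ± 0.46 (adjusted p = 0.00136), YIL102C-A by 4.00 ± 0.98, the mitochondrial glyoxalase GLO4 by 3.60 ± 0.90, TMA46 by 3.32 ± 0.83 and YPR157W by 3.04. YLR243W rose by 3.10 ± 0.89 (adjusted p = 0.0429, and 0.0529 after centring). Cofilin, COF1, fell by 7.22 ± 0.51 (adjusted p = 1.26e-05), with YMR118C at -7.06 ± 0.64, YBR232C, which overlaps PBP2, at -6.78 ± 0.55, DUO1 of the kinetochore at -6.56 ± 0.59, MRPL20 at -6.28 ± 0.64 and YDR015C, which overlaps HED1, at -6.25 ± 0.60. Mitochondrial ribosomal proteins fell in 11 of 33 genes, 13 with 1 up adjusted over the list alone, with MRPS35 at -4.80 and MRPL4 at -4.35 (camera adjusted p = 0.000359, and adjusted p = 0.131 with an estimated correlation). The respiratory chain fell in 5 of 29 genes, also adjusted over the list alone, with ATP2 at -4.21 and CYT1 at -3.94 (camera adjusted p = 0.132). TOM22 was the 1 import gene to fall, at -4.64, and the spindle checkpoint gene MAD2 fell by 5.67, with RPS9B at -3.67. In total 61 genes rose and 270 fell of 3491. The rises numbered 21 without YPGR replicate 1, 33 without YPGR replicate 3, 37 and 36 without YPD replicates 1 and 2, 35 after centring and 173 with a shared spread.

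The same cDNAs fell in several libraries. A total of 91 genes fell in at least 3 of 5 libraries, where shuffling the calls within each library among genes of like abundance gave a mean of 9.38 and at most 19 in 1000 shuffles. Falls in at least 4 libraries numbered 20, and 6 genes fell in all 5. These were CCC1, a vacuolar iron transporter, SBP1, an RNA-binding protein, SDH4 of succinate dehydrogenase, VPS21, an endosomal Rab protein, YNL305C, and YRA2, of the mRNA export family. From starvation to late, YRA2 changed by -5.62, -3.74, -4.56, -6.60 and -2.35, VPS21 by -3.17, -2.76, -3.21, -1.19 and -1.80, and SDH4 by -1.58, -1.22, -2.17, -2.62 and -2.24. In the meiosis II library YRA2 was at 0.793 TPM in YPGR and 159 in YPD. YRA2 (YKL214C) lies on the minus strand of chromosome 11, from 32880 to 33491 in the files' coordinates. Rises were not shared to this degree. At least 2 libraries shared 3 rises, against a mean of 1.95 and at most 8 in 1000 plain shuffles that ignored abundance (where falls in at least 3 libraries had a mean of 4.97 and at most 13), and no rise was shared by 3.

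Of the 91 genes, MRPL20 fell, with a mean change of -6.34 over the 3 libraries in which it was tested (YKR085C, chromosome 11, minus strand, 607401 to 607988). RPS12 fell by 5.92 (YOR369C, chromosome 15, minus strand, 1032523 to 1032954). OPI10 fell by 6.08, with FUN14 at -5.12, the phosphatase inhibitor YPI1 at -4.85, YRA2 at -4.57, TAF14, a subunit of TFIID, at -4.54, TOM40 at -3.81, the Golgi sugar transporter VRG4 at -3.51, phosphatidylinositol synthase PIS1 at -3.48 and COX7 at -3.24. YGL069C, which overlaps MNP1, fell by 4.21, with YIP3, which overlaps YNL043C, at -3.35, and YLR379W, which overlaps SEC61, at -3.32.

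Over the mean of the 5 libraries, some members of 3 mitochondrial gene groups fell. Of 60 mitochondrial ribosomal proteins tested 19 fell, also adjusted over the list alone, and 17 after centring, among them MRPL20 at -3.71 ± 0.19, RSM25 at -3.01 ± 0.27, PET123 at -1.89 ± 0.24 and MNP1 at -1.84 ± 0.22 (camera adjusted p = 1.82e-09, and adjusted p = 1.45e-06 with an estimated correlation). Of 38 respiratory chain genes 10 fell, also adjusted over the list alone, and 9 after centring, with cytochrome c1, CYT1, at -2.21 ± 0.17, COX7 at -1.92 ± 0.27, SDH4 at -1.85 ± 0.14 and QCR6 at -1.43 ± 0.15 (camera adjusted p = 8.92e-05, and adjusted p = 0.00372 with an estimated correlation). Of 22 import genes 6 fell, also adjusted over the list alone. TIM44 fell by 3.07 ± 0.25, with TIM17 at -2.91 ± 0.27, TIM22 at -2.49 ± 0.28, TOM40 at -2.14 ± 0.18 and TIM23 at -2.08 ± 0.20. Before centring the import list's median was -0.09 and its mean -0.67. After centring its median was 0.04, against 0.16 for all tested genes (camera adjusted p = 0.00293, and adjusted p = 0.00596 with an estimated correlation). These 3 groups held their camera call with an estimated correlation.

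Single members of other lists fell as well. Of 104 cytosolic ribosomal proteins 9 fell, 6 after centring, with RPS12 at -3.43 ± 0.25 and RPP0 at -2.36 ± 0.15 (camera adjusted p = 0.135). Actin, ACT1, fell by 1.48 ± 0.13, with COF1 at -1.56 ± 0.18 among 18 cytoskeleton genes (camera adjusted p = 0.688). The chaperone HSP42 fell by 1.73 ± 0.13 (1 of 20, adjusted p = 0.537), with the phosphatase GLC7 and the glucose-sensing regulator MTH1 at -1.18 ± 0.25 and -1.03 ± 0.23 among 22 carbon source regulators (adjusted p = 0.537). REC107 of meiotic recombination fell by 1.23 ± 0.14 among 32 early meiotic genes (adjusted p = 0.537). Before centring FMP45 also fell among 19 spore wall genes (adjusted p = 0.688), and MAD2 and WHI5 among 14 growth brakes (adjusted p = 0.688), and these 3 calls were lost on centring. Adjusted over the list alone, each count before centring was the same. Limma called none of 10 galactose genes, 19 Ras pathway genes, 18 TCA cycle genes, 18 glycolysis genes, 8 histones and 35 middle meiotic genes, of which 5, 11, 7, 6, 1 and 13 had an unadjusted p under 0.05 (camera adjusted p = 0.537, 0.537, 0.135, 0.751, 0.819 and 0.193).

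Genes with 1 direction in all 5 libraries included CAF40 of the CCR4-NOT complex, which rose by 1.35 ± 0.16 (adjusted p = 4.31e-07), PSY4 by 1.33 ± 0.29, the disulfide isomerase MPD2 by 1.33 ± 0.23, the quinone reductase LOT6 by 1.19 ± 0.36 and YBR062C by 1.17 ± 0.34. Leaving aside TIM44 and TIM17, given above, the falls were led by YRA2 at -4.45 ± 0.31 (adjusted p = 3.14e-11) and TAF14 at -4.42 ± 0.33. Next came YLR379W (overlapping SEC61) at -3.20 ± 0.33, YLR339C (overlapping RPP0) at -2.80 ± 0.14 and YBR232C (overlapping PBP2) at -2.77. EMP24 was at -2.77 ± 0.31, the nitrogen regulator URE2 at -2.70 ± 0.18 and the chaperone partner HLJ1 at -2.67 ± 0.17. Of 5230 genes tested 12 rose and 318 fell. With 1 library left out 13 to 28 rose. After centring, which took off a shift of -0.12, 34 rose and 266 fell, and with a pseudocount of 5 the total was 211.

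The effect of the medium differed between libraries in 949 of 5230 genes (limma F test, adjusted p under 0.05). A cDNA near absent from a library cannot fall there, and of the 1177 genes tested in all 5 libraries 263 differed. In 6 genes libraries were called in opposite directions. The chaperonin gene CCT2 fell by 1.15 in meiosis I and rose by 1.34 in late, GDT1 fell by 2.00 in starvation and rose by 2.06 in late, NBP2 fell by 1.67 in meiosis I and rose by 2.21 in meiosis II, and NIP100 rose by 2.90 in early and fell by 3.06 in meiosis II. SEC17, a membrane fusion factor, was at -1.52 in early and -1.71 in meiosis I, both falls, and rose by 1.28 in meiosis II. YLR243W fell in starvation, meiosis I and meiosis II, at -4.64, -5.79 and -4.75, and rose by 3.10 in late.

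The falls built up over the days. On day 1 the mean over libraries gave 44 falls, then 165, 242, 282 and 318 on days 2 to 5. Limma gave 0 rises on days 1, 2 and 3 (769, 1077 and 1254 genes in either direction at an unadjusted p under 0.05), then 8 and 12. YRA2 was already lower on day 1, at -0.58 to -2.05 on the log2 scale across libraries. Mitochondrial ribosomal proteins were not yet called on day 1 (camera adjusted p = 0.296), and 10, 16, 19 and 19 had fallen on days 2 to 5 (camera adjusted p = 4.98e-06, 5.11e-08, 1.05e-08 and 1.82e-09, each with an adjusted p of at most 0.000726 with an estimated correlation). Respiratory chain falls numbered 4, 9, 9 and 10 on days 2 to 5, and import falls 2, 6, 7, 6 and 6 from day 1.

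**Figure D3:**
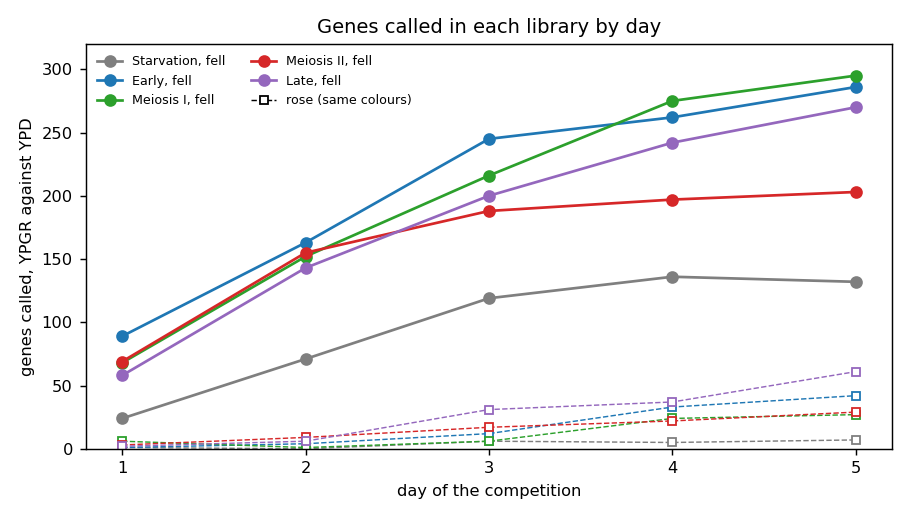
Number of genes called in YPGR against YPD (vertical axis) in each library on days 1 to 5 (horizontal axis), with filled circles and solid lines for falls and open squares and dashed lines for rises. Falls grow from between 24 and 89 on day 1 to between 132 and 295 on day 5, and each library has more falls than rises on every day.

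**Figure D4:**
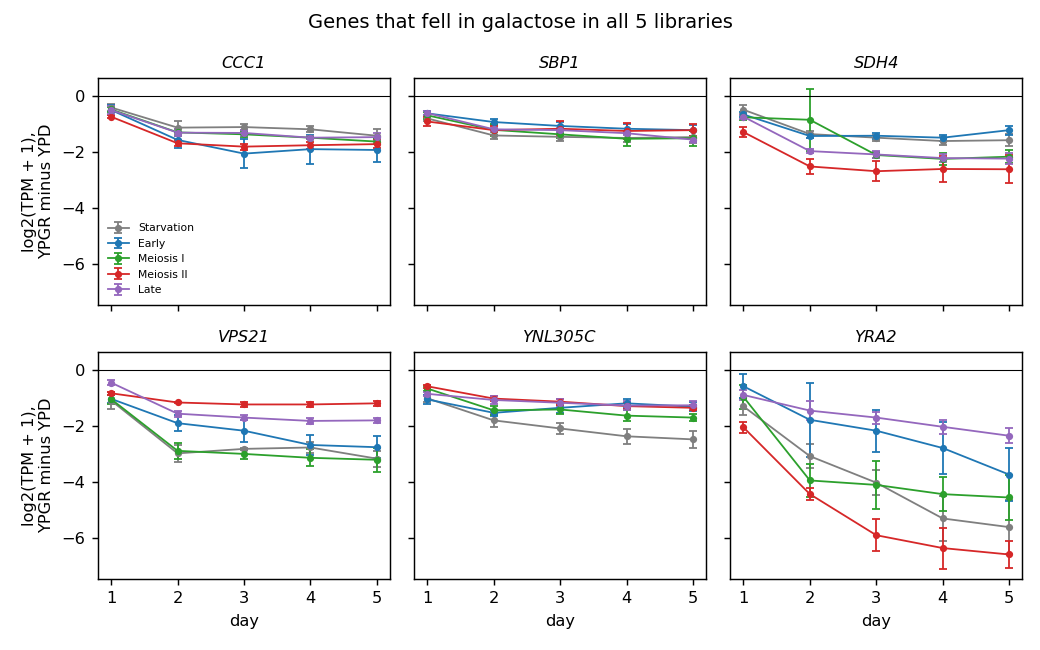
Difference in mean log2(TPM + 1) between YPGR and YPD by day for the 6 genes that fell in all 5 libraries, 1 colour per library. Bars show the standard error of the difference from 3 replicates per medium (2 on day 2 of the early library in YPGR), and YRA2 reaches -6.60 in meiosis II on day 5.

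Within YPD, day 5 was set against day 1 over the 5 libraries (15 samples against 15). The phosphate regulator PHO4 fell by 1.18 before centring, with YGL146C at -1.14 and the zinc transporter ZRT1 at -1.10. They were the 3 genes called by limma and are named for that reason. After centring, which took off a shift of -0.23, these stood at -0.95, -0.91 and -0.87 and were not called, and YHR032W-A rose by 1.08. No gene rose before centring, and 566 of 5242 genes had an unadjusted p under 0.05. The count was 5 without the starvation library or without the meiosis I library, and 1 without the meiosis II library. Limma called no list member, with core histones raised as a group by camera (adjusted p = 0.0472, and adjusted p = 0.0952 with an estimated correlation).

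Within YPGR, day 5 was set against day 1 over the 5 libraries, with the day 5 samples shared with the comparison of the media. YRA2 fell by 3.53 ± 0.21 (adjusted p = 9.02e-12), with TAF14 at -2.90 ± 0.31, RSM25 at -2.75 ± 0.25, TIM44 at -2.58 ± 0.23, YLR379W (overlapping SEC61) at -2.38, CBP3, an assembly factor of the cytochrome bc1 complex, at -2.19 ± 0.27, the ubiquinone synthesis gene COQ2 at -2.11 ± 0.19, YNR042W, which overlaps COQ2, at -1.92, the copper chaperone SCO1 at -1.97 ± 0.15 and YDR352W at -1.88 ± 0.20. Mitochondrial ribosomal proteins fell in 19 cases, 20 adjusted over the list alone and 13 after centring (camera adjusted p = 1.2e-13, and adjusted p = 1.85e-07 with an estimated correlation). The respiratory chain fell in 7 cases, also adjusted over the list alone, and 4 after centring (camera adjusted p = 8.29e-06, and adjusted p = 0.0051 with an estimated correlation), and import in 6, also adjusted over the list alone, and 4 after centring (camera adjusted p = 0.000368, and adjusted p = 0.00232 with an estimated correlation). Of the cytosolic ribosomal proteins 9 fell, also adjusted over the list alone, and 4 after centring. Before centring the list's median was -0.18 and its mean -0.30. After centring its median was 0.13, against 0.24 for all tested genes (camera down, adjusted p = 0.0269, and adjusted p = 0.0207 with an estimated correlation). Of 5261 genes, limma gave 236 falls and no rise, with 1154 at an unadjusted p under 0.05. After centring, which took off a shift of -0.30, 5 rose and 125 fell, and with a pseudocount of 5 the total was 114.

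The spread of each library over its genes was summarised as an effective number of genes, the exponential of the Shannon entropy of the TPM shares. On day 5 the mean difference, YPGR less YPD, was -19.5 over the 5 libraries, a difference that a two-sided permutation test with 100000 resamples did not separate from chance (p = 0.184). On coverage times gene length the sign turned, to 3.7 (permutation p = 0.533). The share of TPM in the 10 most abundant genes was higher in YPGR by a mean of 1.0 percentage points, and higher in 4 of 5 libraries (permutation p = 0.0481). In the meiosis I library the effective number was 386.8 ± 20.6 in YPGR and 432.2 ± 24.4 in YPD, and in the meiosis II library 269.8 ± 1.4 and 283.9 ± 3.0 (SD, n = 3). Each of these had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows. The early library had 660.0 ± 66.1 and 701.3 ± 87.1 (exact p = 0.5), and starvation and late differed by 1.6 and 1.7 (exact p = 1 each). Across the cloning steps the 5 mRNA stages had mean effective numbers of 653.6, 666.2, 605.2, 395.6 and 388.7, the entry vectors 775.2, 1004.7, 781.4, 469.1 and 620.2, the destination vectors 537.9, 912.1, 533.7, 323.2 and 374.1, and the yeast pools 752.4, 1141.3, 592.2, 381.0 and 490.1.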

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

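Of the tests in this part, all splits of the samples, the share of the entry vector sequence, the search for other libraries' sequences, the growth of cells, the F test on genes tested in all 5 libraries and the removal of overlapping genes were chosen after the result was seen, and the others before it.

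From mRNA to entry vector, short genes fell more often, and across genes the Spearman correlation of length with the change was 0.196, 0.316, 0.24, 0.129 and 0.233 from starvation to late (genes are not independent replicates). The entry vector's own sequence, which is signal outside the genes compared, took a mean of 43.2% of TPM (39.8 to 48.2), and a lower share left for genes might explain the falls, but 1035 genes still fell with TPM rescaled over nuclear genes, which argues against it as the whole cause. A length bias of reverse transcription or recombination stays open, since even the lowest correlation, 0.129, is above 0. The different kits for RNA and DNA cannot be told apart from the cloning step, which they share. The next step, with 1 kit throughout, had correlations of opposite sign (-0.173 to -0.101), and no biological explanation was tested.

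In the starvation pool, 30 genes under 1 TPM in both starvation vectors, but with a mean of at least 50 TPM over the destination vectors, had a median of 13.5 TPM, against 0.55 in the destination vector and 0.103 in the entry vector, which is consistent with DNA of other libraries in that pool sample. Growth of such cells is argued against, because the medians of the same genes were 0.414 to 0.522 TPM over the starvation library's day 1 samples in YPD. A change of these cDNAs in yeast itself cannot be told apart for the later libraries, where middle genes had medians of 0.06, 0.15 and 0.25 against 3.09 in starvation. Whether such DNA, if present, entered at the DNA preparation or at sequencing stays open. Genes near absent from a library's own vectors and abundant in another destination vector were set against that source library's pool, gene by gene. In the starvation pool their median was 3.98% of the meiosis I level (10 genes) and 5.28% of the meiosis II level (15 genes). In the early pool it was 1.47% (10 genes) and 2.56% (18 genes). A gene present in both source libraries cannot tell them apart.

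The count of 91 genes that fell in YPGR in at least 3 libraries might reflect abundant genes being called more often, but shuffles among genes of like abundance gave at most 19, which argues against it. Overlapping genes counted together are argued against as well, since 73 of the falls were left without them. A real effect of the induced cDNA or of galactose is consistent with the held-out test, in which genes that fell in at least 2 of the other libraries lay below all 1000 random sets in 5 of 5 held-out libraries, with medians from -1.35 to -0.78. Whether the medium or the induction of the cDNA is responsible cannot be told apart, since no library was grown in galactose without induction. As a hypothesis, induced expression of these cDNAs may slow growth in galactose.

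For each comparison over stages or libraries, 100 splits of the samples were drawn. Chance can be excluded for the mean over libraries (1 split reached the real 330 calls, highest other 74). The same holds for YPGR day 5 against day 1 (236, highest other 165). For the difference between libraries the real count was 949 and the highest other 487. Its splits mix the media within libraries, which removes any effect of the medium and not only a difference in it. They therefore cannot decide whether chance explains the difference between libraries. For YPD day 5 against day 1, 1 split reached the real count of 3 and the highest other was 2. That margin is 1 gene, and none of the 3 calls held on centring, so chance is not excluded there. Both day comparisons used splits that part every replicate pair. For the cloning steps only 14 splits, the real one included, part all 5 stage pairs, too few for a share under 0.05, and the highest other among them was 0 at each step. Over all 100 splits the entry vector had 2605 calls (highest other 753) and the destination vector 306 (highest other 2), each reached by 1 split. Chance cannot be excluded for the yeast pools, where 8 of 100 splits reached the real count of 1 and the highest gave 54. The splits with 54 part only 1 of the 5 stage pairs. With the stage as a block, they rest on the difference within that stage alone. For the single libraries the 10 splits are too few, with real counts of 139, 328, 322, 232 and 331 from starvation to late and a highest other of 0 in each.

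HXT5 stood apart in 1 sample. Its change from entry to destination vector was -4.05 in meiosis II against a median of -3.12 over the 5 stages, a gap of 0.79 of the range, in 1 of 33 groups of named genes examined, and chance gives about 1 in 20. None of 12 groups of libraries had such a sample. The effect of the medium differed between libraries in 949 genes by the F test. Among the 1177 genes tested in all 5 libraries 263 differed. For the 6 genes called in opposite directions the F test uses the samples that picked them and adds no separate evidence, CCT2 (adjusted p = 0.000671), GDT1 (0.000186), NBP2 (0.000451), NIP100 (1.7e-06), SEC17 (1.94e-06) and YLR243W (1.09e-08). Outside the genes compared, mitochondrially encoded genes took a mean of 0.142% of TPM in the yeast pools (0.069 to 0.197), against 0.0082% in the destination vectors. Assembled transcripts that overlap no annotated gene numbered up to 390 per mRNA sample. The sample without a day listed 4669 genes at 5 TPM or more.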

How the results depend on the processing

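Of the tests in this part, TPM rescaled over nuclear genes, days 1 to 4, leaving out overlapped genes or starvation replicate 3, the F test on genes tested in all 5 libraries and camera with a block were chosen after the data were seen. Total counts not named here stayed within 1.5 times. Among 168 results for named genes, 1852 values under alternatives kept call and direction and 204, of 50 results, lost the call, none reversing. Among 67 list results, 301 kept the call and 34, of 16 results, lost it, none reversing. With a pseudocount of 5, calls went to 1030 in meiosis II against meiosis I, 211 in the mean over libraries, 1 in YPD day 5 against day 1 and 114 in YPGR day 5 against day 1. Median centring gave 1040 for meiosis II against meiosis I, 1583 for the entry vector, 94 for the destination vector, 2 for the pools, 1 for YPD and 130 for YPGR day 5 against day 1. Rescaling over nuclear genes gave 1510 for the entry vector and 57 for the destination vector, FPKM gave 2070 for the destination vector, and fits without the stage block 953 and 0 by limma (60 at an unadjusted p under 0.05). The starvation screen had 78 calls with no filter and 313 with a shared spread, and the early screen 590 with a shared spread. The F test gave 263 on the 1177 genes tested in all 5 libraries. Leaving out 1 sample or library at a time gave 190 to 298 calls for the destination vector (190 without early), 1 to 2 for the pools (2 without early), 48 to 147 for the starvation screen (48 and 53 without YPD replicates 1 and 2), 188 to 300 for the early screen (198, 188 and 199 without a YPD replicate) and 1 to 5 for YPD day 5 against day 1 (5 without starvation, 5 without meiosis I, 1 without meiosis II). The lower effective number in YPGR became 3.7 higher on coverage times length (permutation p = 0.533), and the share of the top 10 genes was 1.0 higher in YPGR (p = 0.0481). Beyond the rescaling over nuclear genes, which leaves out the entry vector's share, the cause of these changes was not tested. With a replicate block the counts were 1830, 3387, 1690 and 2082 for the mRNA steps, 191, 261, 291, 227 and 310 for the libraries, 330 for their mean, 1000 for the difference between libraries, and 4 and 239 for YPD and YPGR day 5 against day 1. Under the block 8 results for named genes were not called. Camera with the block, where the numbers were taken to pair the samples, changed no call. In the other libraries' screens same-numbered samples correlated at -0.01 to 0.09, and mRNA replicates at 0.27 to 0.44 between adjacent stages (0.08 to 0.40 over all stages, with genes filtered over all 10 samples). Falls in at least 3 libraries ranged from 65 to 98. Depth could be judged only as aligned megabases, so what it limits was not tested.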

Other observations

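None of the values in this part comes from a test of its own. Several regulators and metabolic genes moved over the whole mRNA course (mean TPM, SD, n = 2), and they were chosen after their values were seen. The strain changed between early and meiosis I, and late mixed both strains. Stage and strain thus cannot be told apart from early to meiosis I or from meiosis II to late. IME1, the master regulator of meiotic entry, stood at 20.8 ± 8.03 in starvation, 5280 ± 3730 at the early stage, 396 at meiosis I, 79.4 at meiosis II and 875 at late. IME4, the mRNA methyltransferase, ran in parallel at 18.6, 4090 ± 1100, 79.1, 35.2 and 477. The metallothionein CUP1-1 (with CUP1-2 a near-identical copy) stood at 45.3, 5200, 97.4, 10.5 and 1630. The leucine genes LEU1 and LEU4 went from 4050 and 1310 in starvation to 72.5 and 25.5 at meiosis I, and LEU2 was listed at 0 in every mRNA sample. NDT80 went from 7.84 in starvation to 70.1 at early and 675 ± 118 at meiosis I, and histone HTA2 from 1080 ± 255 at early to 19.9 at meiosis I.

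GAL7 and GAL1 of the galactose pathway had higher values in the stages whose samples came wholly or partly from the other strain. GAL7 stood at 40.2 at early, 5370 ± 1350 at meiosis I, 6340 ± 1950 at meiosis II and 1770 at late, and GAL1 at 23.6, 119, 105 and 60.1. URA3, a gene of uracil synthesis, stood at 23.1 at early and 182 ± 67 at meiosis I. In the screens URA3 had a mean of 337 TPM in YPD and 827 in YPGR on day 5 in the meiosis I library, 1080 and 2960 in the meiosis II library, and 253 and 447 in the late library (n = 3 each, SDs 42.8 and 59.9, 115 and 657, 50.2 and 57.6). In the other libraries it was lower in YPGR, at 4.26 ± 0.964 in YPD and 0.328 ± 0.218 in YPGR in the starvation library and 1.92 ± 3.13 and 0.134 ± 0.116, near the floor, in the early library. HLR1 stood at 11.7, 29.5, 11.8, 6.82 and 9.17 TPM in mRNA from starvation to late, and at 324, 296, 185, 208 and 150 on day 5 in YPD.

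The sample of the early library in YPGR whose label gives no day had an effective number of 746 genes, 828.7 aligned megabases, 23.0% of its TPM in its top 10 genes and 2.105% in the ribosomal DNA. In the starvation library, YPD replicate 2 on day 3 had a median of 4.43 TPM over the genes taken to mark other libraries, where the next of 30 screen samples had 1.07.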
